A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

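Total RNA of 12 chemostat cultures was analysed, 1 Affymetrix array per culture, in 4 groups of 3: the reference CEN.PK113-7D with air, IMZ305 with air, the reference without oxygen and IMZ383 without oxygen. Per the labels, 200 ng of RNA was amplified and labelled with biotin by a 3' in vitro transcription kit, with the polyadenylated spike-in controls left out. The values deposited by the authors are signal intensities per probe set on a linear scale. The image analysis, summary and scaling software was not given in the sources used here. The mean without the lowest and highest 2% of probe sets was 150.12 to 150.15 on every array, so the authors had scaled the arrays to a common level. A shift of all transcripts in 1 direction would be removed by such scaling, and all changes are relative to the level of the array.

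Of 9335 probe sets, 60 were controls and 9275 were tested. The annotation paired 6504 of these with 1 gene and 328 with several, and gave no gene for 2443; 5656 genes had a probe set of their own. Gene symbols and systematic names follow this annotation. Genome coordinates were used only to find the genes next to the deleted loci, and positions are not given. A gene with several probe sets is represented by the probe set with the highest mean over all arrays. Signals shared between near-identical genes cannot be separated, which holds for FDH1 and FDH2, the PAU, HXT6 and HXT7, IMD and PHO families, and ribosomal protein pairs. The E. coli genes eutE, pflB and pflA were not analysed here. Arrays carry no read counts, and the number of arrays limits the precision. Non-target background was read from 19 bacterial and mouse control probe sets, whose median was 0.5 and whose highest value was 7.5. The design fixed before the data were examined named fission yeast probe sets for this purpose and, since the array had none, its stated substitute was used: a floor at the 10th percentile of all values, 1.1, before log2. Where an array of a group lay under its own highest non-target control, that control replaced its signal and the fold is given as a lower bound ("at least"), and no fold is given where this held in both groups.

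Groups were compared with limma 3.58.1 in R 4.3.3, in a model with 1 mean per group over all 12 arrays, empirical Bayes moderation and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over the 9275 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. "Rose" and "fell" are used for called genes. The comparisons were IMZ305 minus reference with air, IMZ383 minus reference without oxygen, the reference without minus with oxygen, and the difference between both strain effects. Folds are powers of 2 of the log2 change. Fixed gene lists, 32 with 616 entries of which 592 were measured, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera called 12 lists in the aerobic, 19 in the anaerobic and 15 in the oxygen comparison, and with an estimated correlation 3, 7 and 6. The number of members passing when p-values are adjusted over the list alone is given beside the number called over all probe sets. Neighbours of the deleted loci were tested with two-sided, and overlaps with one-sided Fisher's exact tests for more shared probe sets than independent calls give.

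The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the deleted and marker loci, the 10 largest rises and falls per comparison among probe sets with 1 gene whose groups did not overlap and with a mean above the 25th percentile of all values (6.9) in a group, up to 4 called members per list by adjusted p, and the 10 genes in the same and 5 in opposite directions in both strain comparisons. Members named outside it, such as those that make up small counts, and DAN1, AAC3, MGA2, PAU23, HSP42, FET3 and HMG1 in the aerobic comparison, were chosen after their values were seen.

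In data simulated from the spread of the arrays, with 50 probe sets changed at each size, 52% of changes of 1 on the log2 scale were found in the aerobic and the anaerobic comparison and 58% in the oxygen comparison. Changes of 2 were found in 84%, 92% and 88%. False calls made up 8.89% (12 of 135), 3.94% (5 of 127) and 6.67% (9 of 135) of the calls. The aerobic and oxygen shares lay above the nominal 5%, but each comparison was simulated in 1 draw, from a spread pooled over the groups. Differences between the comparisons in any of these percentages therefore come from the draw.

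Alternatives were quantile normalization, median centring of each array, no floor, a floor 2 times as high, a filter on low mean signal, 1 probe set per gene, a fit to only the 2 groups compared, the culture number as a block, an intensity trend with a robust prior, array quality weights, thresholds of 2-fold or of an adjusted p under 0.005, and leaving out each array. Floors of 12 and 50, a block for the BioB hybridization control (above or under 20) and the log2 ratio of the ACT1 3' to 5' signal as a covariate were chosen after the data were seen. Culture numbers did not pair arrays across groups, since arrays with the same number had correlations of residuals from -0.288 to 0.131.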

Results

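Gene expression was measured in glucose-limited chemostat cultures of baker's yeast on 12 Affymetrix 3' arrays, in 4 groups of 3 cultures. CEN.PK113-7D, a laboratory strain with the native enzymes, was the reference and was grown with air and without oxygen. IMZ305, grown with air, lacked the acetaldehyde dehydrogenase genes ALD2 to ALD6 and the acetyl-CoA synthetase genes ACS1 and ACS2, and carried eutE of Escherichia coli, the gene of an acetylating acetaldehyde dehydrogenase, on a plasmid with URA3. IMZ383, grown without oxygen, lacked ACS1 and ACS2 and carried pflB and pflA of E. coli, which encode pyruvate formate-lyase and its activating enzyme, on a plasmid with URA3. All cultures ran at a dilution rate of 0.1 per h, 30 °C and pH 5.0. The feed held 7.5 g/L glucose with air, and 20 g/L glucose plus 10 mg/L ergosterol and 420 mg/L Tween 80 without oxygen.

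Between 74.1% and 84.9% of the yeast probe sets of an array lay above its highest non-target control. The first principal component held 61.8% of the variance and placed the 6 aerobic arrays between -38.93 and -26.88 and the 6 anaerobic arrays between 26.07 and 36.9. The second component (17.4%) parted IMZ305 from the aerobic reference, and the third (7%) parted IMZ383 from the anaerobic reference. Correlations between arrays of a group ran from 0.939 to 0.993 across probe sets, which are not independent replicates. The bacterial hybridization control BioB read 7.9 to 12.0 on 5 arrays (aerobic reference 1 and 2, and the 3 IMZ305 arrays) and 42.9 to 86.2 on the other 7, so within the aerobic comparison this split can be held constant only by leaving out aerobic reference 3. The ratio of the 3' to the 5' signal of ACT1, a sign of RNA or labelling quality, was 1.67 to 1.90 in the anaerobic reference and 1.37 to 1.47 in IMZ383, and overlapped between the aerobic groups (1.24 to 1.96 and 1.61 to 1.65).

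Transcripts of the deleted genes were lost in the engineered strains, and the plasmid marker URA3 rose. In IMZ305, ALD4 (YOR374W) fell from 2899 ± 860 to 1.33 ± 0.404 signal units (mean ± SD, n = 3), at least 616-fold, and ALD6 (YPL061W) fell from 1276 ± 297 to 0.1, at least 275-fold. ACS1 (YAL054C) went from 2047 ± 959 to 0.4 ± 0.1, at least 408-fold lower, and ACS2 (YLR153C) from 765 ± 109 to 1.83 ± 0.379, at least 167-fold lower. ALD5 (YER073W) was at least 59.9-fold lower, ALD3 (YMR169C) at least 7.31-fold lower and ALD2 (YMR170C) at least 5.63-fold lower. In IMZ383, ACS2 fell at least 99.8-fold, from 601 ± 47.6 to 4.87 ± 1.43, and ACS1 fell at least 23.6-fold, from 108 ± 15.4 to 0.433 ± 0.115. ALD6, which is intact in IMZ383, fell from 1053 ± 150 to 301 ± 61.8 (3.52-fold, adjusted p = 0.00166). ALD4 fell there from 1159 ± 63.7 to 537 ± 45 (adjusted p = 0.0394), a call that ended on leaving out any of 8 of the 12 arrays. URA3 (YEL021W) rose from 87.1 ± 3.67 to 2745 ± 89.9 in IMZ305 (31.5-fold, adjusted p = 1.52e-08) and from 64.4 ± 11.1 to 659 ± 66.1 in IMZ383 (10.3-fold, adjusted p = 9.78e-07). LEU2 (YCL018W), which replaced ALD2 and ALD3 in a leu2 mutant background, fell from 1305 ± 126 to 324 ± 42.7 in IMZ305 (4.03-fold, adjusted p = 9.84e-06). In IMZ383, where LEU2 replaced ACS1, it read 2154 ± 36.1 in the reference and 1713 ± 101 in the strain (adjusted p = 0.194). HIS3 (YOR202W) rose 1.44-fold in IMZ305 (adjusted p = 0.0462) and 1.66-fold in IMZ383 (adjusted p = 0.0415), and both calls ended on leaving out single arrays.

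**Figure D1:**
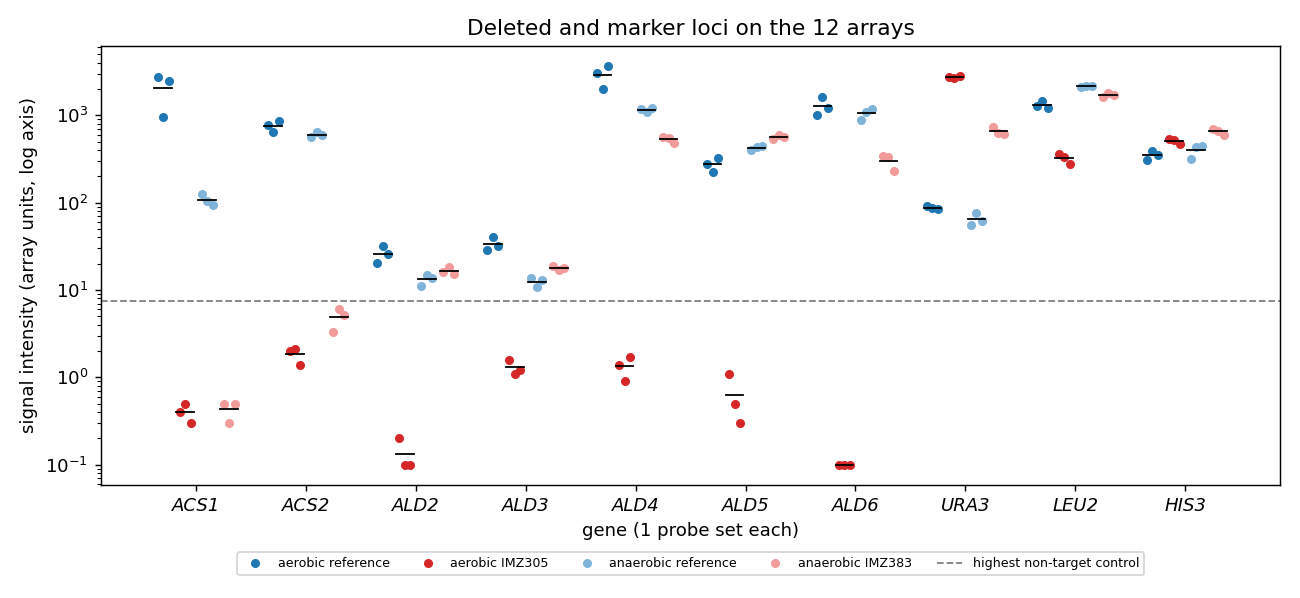
Signal intensity (array units, log axis) of the deleted genes and the marker genes on each of the 12 arrays, 3 points and a black line for the mean per group, with a dashed line at 7.5, the highest non-target control on any array. The deleted genes lie under the line in the strains that lack them, and URA3 lies above the reference on all 6 arrays of the engineered strains.

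The aerobic comparison of IMZ305 with the reference addressed what replacing the native route to cytosolic acetyl-CoA by eutE does to expression under aeration. Strain background, marker genes and the plasmid differed along with the route, so no change can be credited to the route alone. Genes of sterol synthesis were higher in IMZ305, and genes of peroxisomal fatty acid oxidation and of thiamine and biotin supply were lower. FDH1 (YOR388C), the gene of formate dehydrogenase, fell from 1946 ± 347 to 44.9 ± 2.85 (42.9-fold, adjusted p = 6.64e-05). ATF2 (YGR177C), the gene of an alcohol acetyltransferase, rose from 44.1 ± 5.81 to 372 ± 28.5 (8.47-fold, adjusted p = 1.78e-06). YSR3 (YKR053C), which encodes a sphingoid base phosphate phosphatase, rose from 42.3 ± 8.02 to 309 ± 8.96 (7.40-fold, adjusted p = 2.88e-06).

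Of 26 measured genes of sterol synthesis, 17 rose in IMZ305 and 0 fell (20 and 0 adjusted over the list alone), with a median log2 change of 0.78. The list was higher by camera (adjusted p = 3.74e-11, and adjusted p = 0.00657 with an estimated correlation). NCP1, the gene of the reductase that serves the cytochrome P450 steps, rose 2.78-fold, from 304 ± 21.6 to 849 ± 96.7. ERG24 and ERG26, which act on the sterol nucleus, rose 2.40-fold and 1.96-fold, and ERG13, the hydroxymethylglutaryl-CoA synthase gene, rose 1.60-fold. HMG1, which encodes a form of the next enzyme, had a log2 change of 0.21 and was not called.

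Of 18 genes of beta-oxidation and peroxisomes, 12 fell and 0 rose (14 and 1 adjusted over the list alone), with a median log2 change of -0.995. This list was lower by camera (adjusted p = 2.18e-08, and adjusted p = 0.00565 with an estimated correlation). ECI1, an enoyl-CoA isomerase gene, fell 5.18-fold, from 434 ± 124 to 82.3 ± 13. CTA1, the peroxisomal catalase gene, fell 3.94-fold, POT1, the thiolase gene, 2.86-fold, and PXA1, a fatty acid transporter gene, 2.52-fold. FAT3, whose product takes part in fatty acid uptake, fell 10.01-fold, from 365 ± 64.6 to 36.4 ± 5.

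The list of general stress, trehalose and glycogen genes had 14 of 25 members lower and 1, HSP42, higher (15 and 1 adjusted over the list alone), with a median log2 change of -0.53. Camera gave an adjusted p = 3.12e-06, but an adjusted p = 0.0928 with an estimated correlation. The members that fell most clearly were the glycogen genes GPH1 (3.70-fold), GSY2 (3.27-fold) and GAC1 (3.45-fold), while HSP26, a small heat shock protein gene, fell 1.69-fold from 2048 ± 282 to 1207 ± 33.5. SPG1 and SIP18, genes expressed in stationary phase and under salt stress, fell 12.0-fold and 7.83-fold. Of 16 thiamine and biotin genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 1.60e-05, and adjusted p = 0.0447 with an estimated correlation). The thiamine transporter gene THI7 fell 2.70-fold, the biotin pathway gene BIO5 3.39-fold, and PHO3, a thiamine-repressed acid phosphatase gene, 3.37-fold. The stress list had 9 members lower without aerobic reference 1 and 8 without IMZ305 replicate 2, with 0 higher without any 1 of the 6 arrays compared but aerobic reference 3, and the thiamine and biotin list had 5 lower without aerobic reference 1 or IMZ305 replicate 1 or 3.

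The list of 22 hypoxic and anaerobic genes also held regulators, such as ROX1 and MGA2. Of these 22, 7 rose in aerated IMZ305 (YSR3, TIR3, TIR1, ARE1, DAN1, AAC3 and PAU23, the last of a family with near-identical sequences) and 1, MGA2, fell (11 and 1 adjusted over the list alone). The median log2 change was 0.54 and the camera adjusted p = 0.00018, with an adjusted p = 0.215 with an estimated correlation. TIR1 and TIR3, cell wall mannoprotein genes, rose from 93.7 ± 8.31 to 280 ± 49.8 and from 105 ± 25.7 to 387 ± 112. Among the low-BioB arrays, 8 members were higher and 1 lower, with a median of 0.47.

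Of 16 mating genes, 5 fell and 0 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00246, and adjusted p = 0.0984 with an estimated correlation), among them MF(ALPHA)1, from 56.3 ± 11.2 to 5.37 ± 3.5, and MFA2, 2.12-fold; the others were MFA1, AGA2 and STE4. Of 8 arginine genes, 2, ARG8 and ARG3, rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.14 with an estimated correlation). Of 12 branched-chain amino acid genes, ILV1, BAT1 and BAT2 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.00871, and adjusted p = 0.271 with an estimated correlation). Glycerol metabolism had 4 of 11 members lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00814, and adjusted p = 0.106 with an estimated correlation), GUT1, the glycerol kinase gene, which fell 3.91-fold, and STL1, GCY1 and FPS1. Hexose transport and sugar use also had 4 of 19 lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.00871, and adjusted p = 0.106 with an estimated correlation), HXT10, HXT6, MTH1 and the hexokinase gene HXK1, which went from 2801 ± 56.9 to 1700.2 ± 12. In sulfur metabolism 3 of 24 genes rose, CYS3, MUP1 and MET8, and 2 fell, MET32 and SUL1 (3 and 2 adjusted over the list alone; camera adjusted p = 0.0359, and adjusted p = 0.106 with an estimated correlation). Of 81 ribosomal protein genes, 4 rose, among them RPL13B, RPS28B and RPL16B, and 1, RPS26B, fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.00396, and adjusted p = 0.466 with an estimated correlation). Several of these counts changed on leaving out 1 array. Without aerobic reference 1, IMZ305 replicate 1 or IMZ305 replicate 2, 3 mating genes and 1 glycerol gene were lower and 1 branched-chain gene was higher, and 2 glycerol genes were lower without aerobic reference 3 or IMZ305 replicate 3. Without aerobic reference 2, 1 mating gene was higher. Of the arginine genes, 1 was higher without aerobic reference 3 or IMZ305 replicate 1 or 2, and 1 sulfur gene was lower without any 1 of the 6 arrays compared but aerobic reference 1. Ribosomal protein genes numbered 0 higher without IMZ305 replicate 1 or 2, 2 without IMZ305 replicate 3 and 8 without aerobic reference 2.

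Several lists held genes that went both ways. In the nitrogen list, 7 of 27 genes rose, among them the amino acid permease genes BAP3 (at least 2.66-fold) and AGP1 (2.90-fold), and 8 fell, among them GDH3 (5.13-fold); 10 rose and 9 fell adjusted over the list alone, and camera gave an adjusted p = 0.845. In the iron and copper list, FTR1, FET3 and TIS11 rose and the copper transporter genes CTR3 (5.43-fold) and CTR1 (2.91-fold) and FRE4 fell, 3 and 3 of 21 also adjusted over the list alone (camera adjusted p = 0.375). CIT2, the peroxisomal citrate synthase gene, rose from 538 ± 229 to 1315 ± 33.5, while ADR1, which encodes an activator of peroxisomal and ethanol-use genes, fell 2.16-fold. They belonged to a list of 11 glyoxylate and gluconeogenesis genes with 1 higher and 4 lower, ADR1, SFC1, FBP1 and IDP2 (2 and 5 adjusted over the list alone; camera adjusted p = 0.47). PHO5 (YBR093C), the repressible acid phosphatase gene, rose from 0.333 ± 0.252, under the non-target controls, to 55.3 ± 4.29, at least 9.21-fold, whereas the 15 phosphate genes as a list had 2 higher, PHO5 and PHO89, and 2 lower, PHO3 and VTC2 (4 and 3 adjusted over the list alone; camera adjusted p = 0.45), with a median log2 change of -0.004 and a mean of 0.28. Of 12 one-carbon and formate genes, ADE3 rose and FDH1 and FOL1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.674), with a median of 0.11 and a mean of the other sign, -0.42. Of 11 weak-acid response genes, TPO2 and PHM8 rose and PDR12 and GPG1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.388). Among 29 genes of histone acetylation, deacetylation and silencing limma called 0 (0 adjusted over the list alone), with 7 at an unadjusted p under 0.05. In the nitrogen list, 4 were higher without aerobic reference 1 and 3 without IMZ305 replicate 1 or 3, and 5 were lower without aerobic reference 3 or IMZ305 replicate 3 and 4 without IMZ305 replicate 2. In the glyoxylate and gluconeogenesis list, 2 were lower without aerobic reference 3 or IMZ305 replicate 2 and 1 without IMZ305 replicate 1, and 2 were higher without aerobic reference 1. In the phosphate list 1 was lower without aerobic reference 1 or IMZ305 replicate 1 or 2, in the one-carbon list 1 was lower without any 1 of the 6 arrays and 0 were higher without aerobic reference 3 or IMZ305 replicate 1 or 2, and in the weak-acid list 1 was higher without any 1 array but aerobic reference 1.

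Among the largest single changes in IMZ305, the small open reading frame YDR034C-A rose 15.0-fold, from 44.5 ± 33.1 to 443 ± 39.6, and PBI1 (YPL272C) rose 10.5-fold, from 10 ± 2.88 to 103 ± 5.76. YMR317W, of unknown function, rose at least 10.02-fold, YJL213W 7.19-fold, and YPR145C-A 6.62-fold, while JLP1, a sulfonate dioxygenase gene, rose from 1.07 ± 0.231 to 11.4 ± 7.84, with arrays under background in both groups. FDH1 also fell at its other probe set, 69.8-fold. CRF1, which encodes a corepressor of ribosomal protein genes, fell 11.7-fold, from 211 ± 24.2 to 18.0 ± 2.33. ECM29, at 1 of its 8 probe sets, and CMG1 fell at least 2.92-fold and at least 2.72-fold. PRR2, a kinase gene, fell 8.07-fold and IMA5, an isomaltase gene, at least 4.46-fold, calls that ended on leaving out any of 4 and any of 9 of the 12 arrays.

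In total 565 of 9275 probe sets were higher and 770 lower in IMZ305 (limma), 267 and 295 of them by at least 2-fold, which covered 408 and 621 of 5656 genes. The direction split depended on the scaling here too: 42.3% of the calls were higher as deposited, 45.7% with quantile normalization and 50.3% with median centring. The 2 groups did not overlap for 31.1% of probe sets, against 10% by chance. Without aerobic reference 3, among the low-BioB arrays, 455 were higher and 570 lower. Fewer were called without IMZ305 replicate 1 (305 higher and 396 lower) or 2 (277 and 389), and 498 were lower without aerobic reference 1. IMZ305 replicates 1 and 2 were the most alike pair of arrays, with a correlation of 0.993 against at most 0.983 for any other pair within a group.

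**Figure D2:**
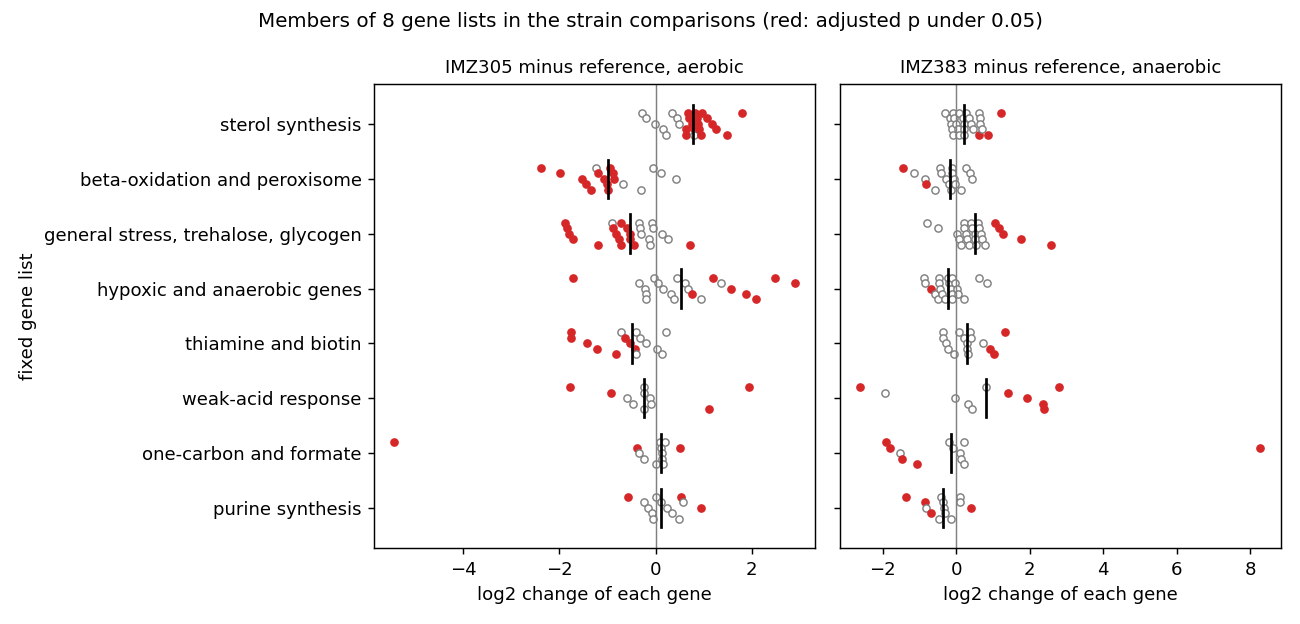
Log2 change of each measured gene in 8 of the fixed lists, left for IMZ305 against the aerobic reference and right for IMZ383 against the anaerobic reference, with called genes filled in red and a black bar at the median of the list. Most sterol genes lie to the right of 0 and most beta-oxidation genes to the left in the aerobic panel (medians 0.78 and -0.995), and the stress list has its median at -0.53 in the aerobic and 0.50 in the anaerobic panel.

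The anaerobic comparison of IMZ383 with the reference addressed the same replacement by pyruvate formate-lyase, an enzyme that also releases formate, in the absence of oxygen. Background, marker genes and the plasmid differed along with the replacement here as well. FDH1 rose from 2.17 ± 1.61, under the non-target controls, to 590 ± 108 (at least 112-fold, adjusted p = 8.57e-06). The glycine cleavage genes GCV1, GCV2 and GCV3 fell 3.74-fold, 3.48-fold and 2.77-fold, with GCV1 (YDR019C) going from 584 ± 29.6 to 156 ± 17.2 (adjusted p = 3.96e-05). Of the stress and the weak-acid response lists, 5 genes each rose, among them HSP26 (YBR072W), from 175 ± 17.9 to 1044 ± 138 (5.96-fold, adjusted p = 1.14e-05). PDR12 (YPL058C), the gene of a carboxylate efflux pump, fell from 414 ± 114 to 67.2 ± 13.8 (6.07-fold, adjusted p = 0.00121).

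In the list of one-carbon and formate genes, 1 of 12, FDH1, rose, and 4 fell, among them SHM2, a serine hydroxymethyltransferase gene, 2.10-fold (1 and 5 adjusted over the list alone). The list was lower by camera (adjusted p = 0.0022, and adjusted p = 0.115 with an estimated correlation), with a median log2 change of -0.14, while its mean of 0.08 had the other sign. Of 13 purine genes, 3, ADE1, ADE4 and ADE17, fell and 1, ADE16, rose (5 and 1 adjusted over the list alone; camera adjusted p = 7.06e-05, and adjusted p = 0.0343 with an estimated correlation). ADE1 fell 2.57-fold and ADE17 1.80-fold, calls that ended without anaerobic reference 3. The calls of ADE1, ADE4 and ADE17 also ended with the ACT1 ratio as a covariate, and no list was tested with it. The purine list had 0 lower without that array and 1 without anaerobic reference 2, and 0 higher without either or without IMZ383 replicate 1 or 2.

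Of 25 stress, trehalose and glycogen genes, 5 rose and 0 fell (13 and 1 adjusted over the list alone), with a median log2 change of 0.50 (camera adjusted p = 1.34e-07, and adjusted p = 0.0343 with an estimated correlation). DDR2 rose 3.40-fold, from 779 ± 57.3 to 2644 ± 98.8, HSP12 2.26-fold and SPI1 2.07-fold; the others were HSP26 and TSL1. Of 11 weak-acid response genes, 5 rose and 1, PDR12, fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.00136, and adjusted p = 0.0343 with an estimated correlation). TPO2, a polyamine and acetate exporter gene, rose 5.28-fold, YGP1 5.11-fold and YRO2 6.96-fold, and MRH1 and PHM8 rose as well.

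QDR2 (YIL121W), a drug transporter gene, rose from 11.4 ± 1.95 to 153 ± 23.9 (13.4-fold, adjusted p = 8.27e-05) and its paralog AQR1 (YNL065W) fell from 86.3 ± 13.7 to 15 ± 1.05 (5.72-fold, adjusted p = 0.000392). OPT2, an oligopeptide transporter gene, fell at least 15.0-fold, from 88.3 ± 42.5 to 3.63 ± 0.764. YHL008C, of the formate and nitrite transporter family, rose 5.59-fold, HXT5, a hexose transporter gene, 5.18-fold, and ATO2, of the ammonium and acetate transporter family, fell 3.82-fold. INO1, the inositol synthesis gene, fell 4.30-fold, in a list of 17 phospholipid genes with 1 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.00204, and adjusted p = 0.0343 with an estimated correlation). Without IMZ383 replicate 2, 2 phospholipid genes were lower. EEB1, which encodes an ethyl ester synthase, fell 3.76-fold. ROG3 rose at least 1.59-fold, while CDA2 fell at least 2.77-fold and YDL114W fell from 8.3 ± 5.33 to 1.43 ± 0.153, with arrays under background in both groups, calls that ended on leaving out any of 9 and any of 11 of the 12 arrays.

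Single genes of biosynthesis rose in IMZ383 against the anaerobic reference. URA1, the dihydroorotate dehydrogenase gene, rose 3.72-fold, LEU1 3.66-fold and OAC1, a mitochondrial carrier gene, 3.04-fold; the last pair and BAT1 were the 3 of 12 branched-chain genes called higher (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.178). HMG1, ERG5 and ERG13 were the 3 of 26 sterol genes that rose, with 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.00652, and adjusted p = 0.115 with an estimated correlation), HMG1 from 376 ± 26.9 to 870.3 ± 64.1. BIO3, BIO4 and BIO5 were the 3 of 16 thiamine and biotin genes that rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0255, and adjusted p = 0.174 with an estimated correlation). FTR1, TIS11 and HMX1 rose among 21 iron and copper genes (4 and 0 adjusted over the list alone; camera adjusted p = 0.0102, and adjusted p = 0.313 with an estimated correlation), and PHO5 rose from 0.267 ± 0.0577 to 88.9 ± 8.5, at least 17.0-fold. Without anaerobic reference 1, 7 iron and copper genes were higher. Of the branched-chain genes, 1 was higher without anaerobic reference 2 or IMZ383 replicate 2, and 1 was lower without IMZ383 replicate 1.

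Some lists shifted by camera with few genes called. Of 15 tricarboxylic acid cycle genes limma called 0 (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), with a median log2 change of -0.31 (camera adjusted p = 2.38e-05, and adjusted p = 0.0343 with an estimated correlation). Of 32 respiratory chain genes limma called 0 (1 higher and 2 lower adjusted over the list alone, 8 at an unadjusted p under 0.05), with a median of -0.20 (camera adjusted p = 6.73e-05, and adjusted p = 0.139 with an estimated correlation). POT1 and SPS19 were the 2 of 18 beta-oxidation genes that fell (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.0343 with an estimated correlation). AGA2 and FUS3 were the 2 of 16 mating genes that fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.000325, and adjusted p = 0.0343 with an estimated correlation). YSR3 was the only 1 of 22 hypoxic genes called, and it fell, from 394 ± 36.9 to 246 ± 25.9 (adjusted p = 0.0402), a call that ended on leaving out any of 9 of the 12 arrays. The hypoxic list had 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00656, and adjusted p = 0.313 with an estimated correlation). Of 11 glyoxylate and gluconeogenesis genes, SIP4 and MDH2 rose (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00788, and adjusted p = 0.313 with an estimated correlation). Of 16 pentose phosphate and NADPH genes, SOL4 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0344, and adjusted p = 0.115 with an estimated correlation). Of the 6 arrays compared, leaving out any but anaerobic reference 2 gave 1 lower beta-oxidation gene, any but IMZ383 replicate 2 gave 1 lower mating gene, and any but anaerobic reference 2 and IMZ383 replicate 2 gave 1 higher glyoxylate gene. Pentose phosphate genes numbered 2 higher without IMZ383 replicate 3 and 0 without any 1 of the other 5, and 1 respiratory chain gene was lower without IMZ383 replicate 3.

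The amino acid and chromatin lists held few called genes. Of 27 nitrogen and amino acid uptake genes, MEP2 and CAR1 rose and GDH3 fell (2 and 5 adjusted over the list alone), and the list was lower by camera (adjusted p = 0.0164, and adjusted p = 0.115 with an estimated correlation). Of 8 arginine genes limma called 0 (1 higher adjusted over the list alone, 4 at an unadjusted p under 0.05), with a median log2 change of 0.42 (camera adjusted p = 0.00652, and adjusted p = 0.152 with an estimated correlation). Of 29 genes of histone acetylation, deacetylation and silencing, EPL1 rose (2 and 0 adjusted over the list alone). This mixed list was higher by camera (adjusted p = 0.0139, and adjusted p = 0.335 with an estimated correlation). Of 81 ribosomal protein genes limma called 0 (0 adjusted over the list alone, 5 at an unadjusted p under 0.05), with a median of -0.08 (camera adjusted p = 0.000401, and adjusted p = 0.313 with an estimated correlation), a camera call that ended with quantile normalization. In the nitrogen list 1 was higher without anaerobic reference 2 or 3 or IMZ383 replicate 1 or 3, and 0 were lower without anaerobic reference 3 or IMZ383 replicate 2. Without anaerobic reference 1, 2 genes of the list of histone acetylation, deacetylation and silencing were higher.

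In total 157 probe sets were higher and 55 lower in IMZ383 (limma), 88 and 40 of them by at least 2-fold, which covered 131 and 45 genes. The share of calls that were higher, 74.1%, depended on the scaling and was 60.4% with quantile normalization and 54.4% with median centring, which moved the median log2 change of all probe sets from 0.06 to 0 and -0.06. The 2 groups did not overlap for 19.8% of probe sets, against 10% by chance. The count of higher probe sets was 93 without anaerobic reference 3 and 103 without IMZ383 replicate 1, and 36 were lower without anaerobic reference 2. With the ACT1 ratio, which parted these groups, as a covariate, 95 were higher and 29 lower, and 34 of the 82 named calls ended, among them those of ALD4, HIS3, INO1, ADE1, ADE4, ADE17, LEU1, POT1 and YSR3, while FDH1, GCV1, GCV2, GCV3, HSP26, PDR12 and QDR2 were still called.

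**Figure D3:**
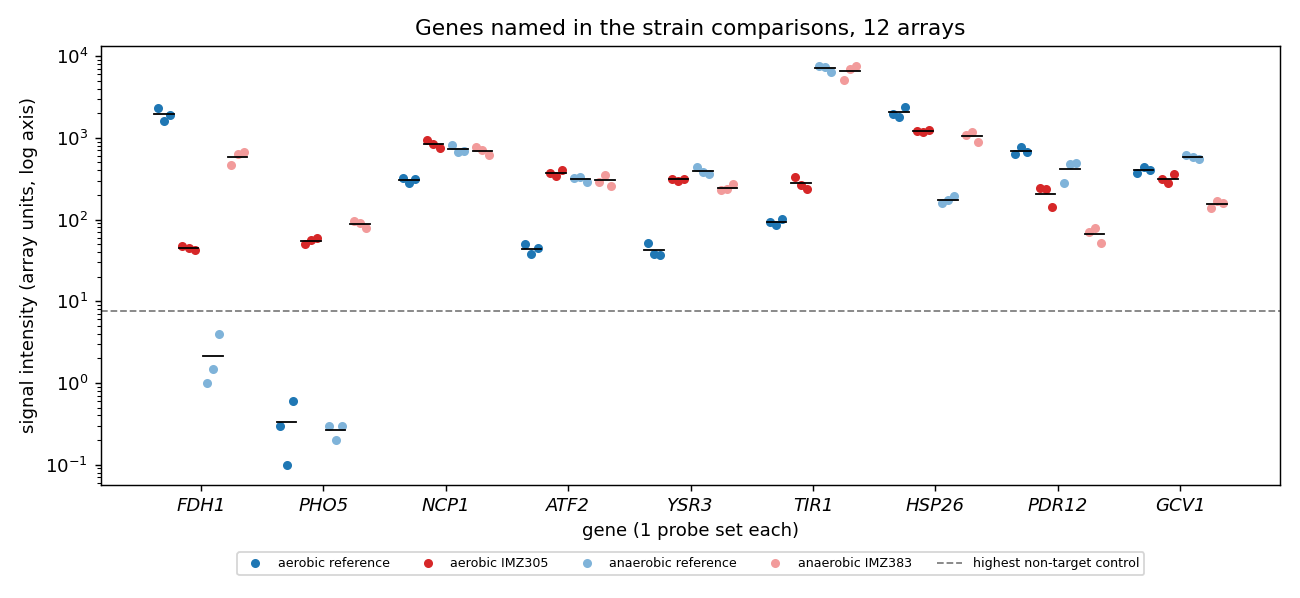
Signal intensity (array units, log axis) of 9 genes on each of the 12 arrays, 3 points and a black line for the mean per group, with a dashed line at 7.5, the highest non-target control on any array. FDH1 is low in aerobic IMZ305 (mean 44.9) and high in anaerobic IMZ383 (mean 590), and PHO5 lies under the dashed line on all 6 reference arrays.

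The comparison of the reference strain without and with oxygen gave the size of the response to the conditions themselves, and the glucose feed, ergosterol, Tween 80 and antifoam changed along with oxygen. Hypoxic genes were higher without oxygen, and genes of the respiratory chain, of peroxisomal fatty acid oxidation and of the carnitine shuttle and acetate transport were lower. DAN1 (YJR150C), a cell wall mannoprotein gene, rose from 6.03 ± 3.74 to 3388 ± 294 (at least 488-fold, adjusted p = 1.73e-06), and ANB1 (YJR047C), the hypoxic translation factor gene, from 15 ± 3.75 to 3174 ± 210.3 (216-fold, adjusted p = 1.53e-07). ADH2 (YMR303C), the ethanol-oxidizing alcohol dehydrogenase gene, fell from 5162 ± 568 to 20.7 ± 1.45 (248-fold, adjusted p = 2.57e-09).

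Of 22 hypoxic genes, 17 rose and 1, ROX1, fell (17 and 1 adjusted over the list alone; camera adjusted p = 1.57e-16, and adjusted p = 0.0407 with an estimated correlation). TIR1 rose 75.5-fold, TIR3 34.7-fold, YSR3 9.40-fold and AAC3, the hypoxic ADP/ATP carrier gene, at least 31.4-fold. All 18 beta-oxidation and peroxisome genes fell (18 adjusted over the list alone), with a median log2 change of -2.61 (camera adjusted p = 2.50e-13, and adjusted p = 0.00105 with an estimated correlation). CTA1 fell 218-fold, FOX2, a multifunctional beta-oxidation enzyme gene, 25.1-fold and PXA1 21.5-fold. Of 32 respiratory chain genes, 28 fell and 0 rose (31 and 0 adjusted over the list alone; camera adjusted p = 6.37e-12, and adjusted p = 0.0407 with an estimated correlation), among them COX5A (4.97-fold), CYT1 (3.43-fold) and NDE1 (11.6-fold).

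Of 11 glyoxylate and gluconeogenesis genes, 10 fell and 1, CIT2, rose (10 and 1 adjusted over the list alone; camera adjusted p = 6.32e-09, and adjusted p = 0.0544 with an estimated correlation), among them SFC1 (at least 102-fold), FBP1 (at least 37.9-fold) and ICL1 (10.7-fold). Of 11 carnitine shuttle and acetate transport genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 8.13e-06, and adjusted p = 0.0407 with an estimated correlation), with JEN1, the lactate and pyruvate permease gene, going from 2341 ± 469 to 49.2 ± 6.33. Of 15 tricarboxylic acid cycle genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.000951, and adjusted p = 0.0407 with an estimated correlation). Of 25 stress genes, 16 fell and 2, GSY1 and TPS3, rose (17 and 3 adjusted over the list alone; camera adjusted p = 7.97e-05, and adjusted p = 0.0951 with an estimated correlation), with HSP26 11.7-fold and GRE1 36.9-fold lower. Of 21 iron and copper genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 0.000546, and adjusted p = 0.143 with an estimated correlation), and of 16 thiamine and biotin genes 10 fell and 1, BIO2, rose (1 rose and 12 fell adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.0767 with an estimated correlation). Of 16 pentose phosphate and NADPH genes, 9 fell and 4 rose, ZWF1, RPE1, TKL1 and IDP1 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0441, and adjusted p = 0.116 with an estimated correlation), and of 11 weak-acid response genes 7 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0292, and adjusted p = 0.0951 with an estimated correlation). Of the glyoxylate genes 0 were higher without aerobic reference 3 or anaerobic reference 2, 0 stress genes were higher without aerobic reference 3 and 1 without anaerobic reference 1 or 2, and 1 weak-acid gene was higher without aerobic reference 3.

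Higher without oxygen were 9 of 13 purine genes, with 1, ADE16, lower (10 and 1 adjusted over the list alone; camera adjusted p = 1.97e-05, and adjusted p = 0.0407 with an estimated correlation), and 6 of 12 branched-chain genes, with 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.000951, and adjusted p = 0.143 with an estimated correlation). IMD2, an inosine monophosphate dehydrogenase gene with close paralogs, rose 3.77-fold. Of 81 ribosomal protein genes, 20 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 1.89e-08, and adjusted p = 0.143 with an estimated correlation), and the camera call ended with quantile normalization. The count of higher ribosomal protein genes was 12 without aerobic reference 3, 9 without anaerobic reference 2 and 8 without anaerobic reference 3, and 1 was lower without anaerobic reference 1. Sterol genes went both ways, with 8 of 26 higher, among them NCP1 (2.40-fold), and 7 lower, among them HMG1 (5.99-fold) and IDI1 (3.16-fold); the counts were also 8 and 7 adjusted over the list alone. Their median log2 change of -0.08 and the direction of the camera test, which was up, differed in sign (camera adjusted p = 0.446). Of 16 mating genes, 5 rose, BAR1, FUS3, STE2, MFA2 and FUS1, and 2 fell, GPA1 and SAG1 (5 and 3 adjusted over the list alone; camera adjusted p = 0.0353, and adjusted p = 0.143 with an estimated correlation). Sterol genes numbered 5 higher without anaerobic reference 2 and 4 without anaerobic reference 3, and mating genes 0 lower without aerobic reference 1 or 2 or anaerobic reference 3 and 1 without anaerobic reference 2. Single genes with large changes were FLO11, a flocculin gene (44.6-fold higher), BAP3 (at least 16.4-fold higher), OPT2 (at least 13.4-fold higher), CYB2, a lactate dehydrogenase gene (79.4-fold lower), and FDH1 (at least 369.9-fold lower). HUG1, a gene of the DNA damage response, rose 43.0-fold, and HMS1 and YML083C, under background with air, rose at least 9.27-fold and at least 7.90-fold. SUE1, whose product acts on cytochrome c, fell at least 129-fold, ADY2, an acetate transporter gene, at least 81.7-fold, SPG1 at least 70.6-fold, PUT4, a proline permease gene, 63.0-fold and YIG1 at least 53.9-fold. ACS1 fell 17.4-fold, and ACS2 read 765 ± 109 with and 601 ± 47.6 without oxygen (adjusted p = 0.315).

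In total 1018 probe sets were higher and 2157 lower without oxygen (limma), 623 and 1050 of them by at least 2-fold, which covered 570 and 1837 genes. The direction split depended on the scaling: 32.1% of the calls were higher as deposited, 48.9% with quantile normalization and 67.6% with median centring, which moved the median log2 change of all probe sets from -0.18 to 0 and 0.22, so changes are best read relative to that shift. The 2 groups did not overlap for 42.7% of probe sets, against 10% by chance. Only aerobic reference 3 shared the high BioB reading with the anaerobic reference arrays. With the BioB split as a block, the oxygen comparison rests on that 1 aerobic array, so its counts are not given.

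The effects of IMZ305 and IMZ383 were compared directly, although genotype and oxygen differ together between them. Some genes changed in the same direction in both strains and others in opposite directions, with FDH1 the most extreme of the latter. PDR12 fell 3.43-fold in IMZ305 and 6.07-fold in IMZ383, and POT1 fell 2.86-fold and 2.71-fold. PHO5 and TPO2 rose in both, TPO2 3.86-fold and 5.28-fold. The iron permease gene FTR1 rose 2.35-fold and 3.12-fold, and ARO10, a decarboxylase gene of amino acid breakdown, rose 3.04-fold in IMZ305 and at least 1.70-fold in IMZ383. ALP1, an amino acid transporter gene, fell 1.68-fold and at least 2.02-fold, CHA1, a serine deaminase gene, rose at least 2.45-fold and at least 2.70-fold, and YPR145C-A rose 6.62-fold and 2.16-fold. ROG3 was called higher in both, though at 3.77 ± 1.11 in IMZ305 it lay near the non-target controls. NCA3 fell 2.89-fold in IMZ305 and rose 5.06-fold in IMZ383, and MBR1 (2.60-fold and 2.06-fold) and DCS2 (2.07-fold and 2.03-fold) did likewise, as did YMR181C, with log2 changes of -0.93 and 0.59.

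Both comparisons called 29 probe sets higher, where 9.6 were expected from independent calls (Fisher's exact p = 6.09e-08), and 17 lower, where 4.6 were expected (Fisher's exact p = 1.19e-06). In opposite directions, 39 were lower in IMZ305 and higher in IMZ383, with 13 expected (Fisher's exact p = 2.63e-10), and 9 were higher in IMZ305 and lower in IMZ383, with 3.4 expected (Fisher's exact p = 0.00556). These tests treat probe sets as independent, which they are not. The deleted and marker genes were kept in them. ACS1 and ACS2, deleted in both strains, and ALD4 and ALD6, deleted in IMZ305, count among the shared lower calls. URA3 and HIS3 count among the shared higher calls. More were shared than expected in every direction, opposite ones included, so the excess does not by itself show a common response. The difference between the effects itself was called for 823 probe sets, 274 with the more positive change in IMZ305 and 549 with the more positive change in IMZ383. Its median over all probe sets was -0.08, and this split was not examined under other scalings. HSP26 differed by -3.33 on the log2 scale (SE 0.19, adjusted p = 1.55e-05), ATF2 by 3.15 (SE 0.20, adjusted p = 3.35e-05), YSR3 by 3.57 (SE 0.20, adjusted p = 1.38e-05) and GCV1 by 1.56 (SE 0.17, adjusted p = 0.00102). For PDR12 (adjusted p = 0.231), POT1 (adjusted p = 0.92) and FTR1 (adjusted p = 0.507) the difference was not called, nor for TPO2 (adjusted p = 0.524), ARO10 (adjusted p = 0.556), ALP1 (adjusted p = 0.366), CHA1 (adjusted p = 0.845) and ROG3 (adjusted p = 0.136). It was called for YPR145C-A (1.62, adjusted p = 0.00193) and PHO5 (-0.68, adjusted p = 0.0119). For PHO5 both references lay at the floor, which cancels, so its value only sets IMZ305 with air against IMZ383 without oxygen. With the ACT1 ratio as a covariate, 25 probe sets were called in the same direction in both strains, against 46. The 48 probe sets with opposite calls were 18 without IMZ305 replicate 2, 29 without IMZ305 replicate 1, 26 without anaerobic reference 3 or IMZ383 replicate 1, and 27 without IMZ383 replicate 2. The count of called differences was 479 without IMZ305 replicate 2, 515 without replicate 1 and 517 without anaerobic reference 3.

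**Figure D4:**
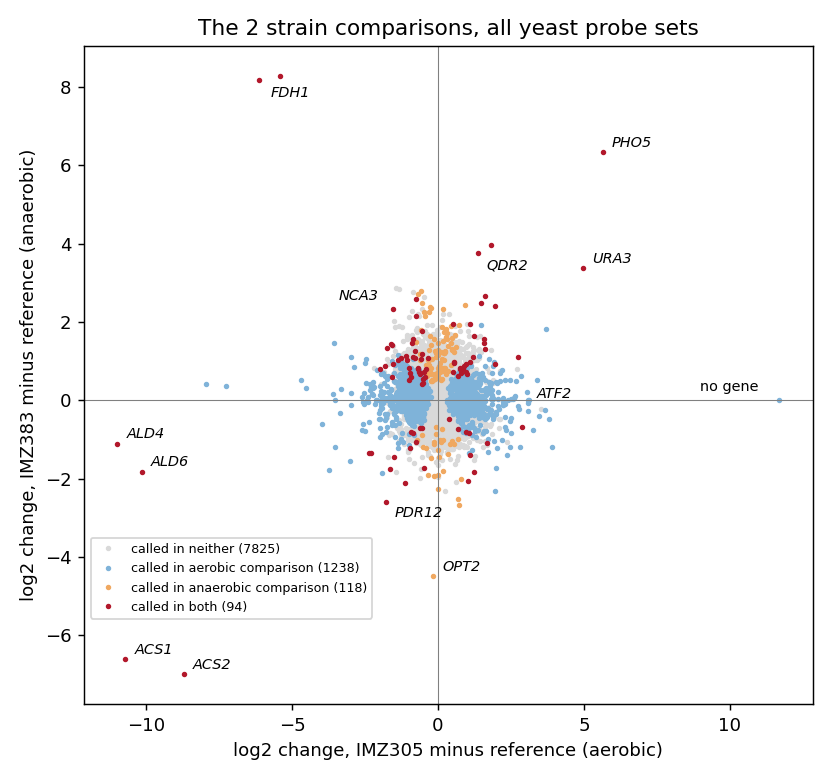
Log2 change of each of the 9275 yeast probe sets in IMZ305 against the aerobic reference (horizontal axis) and in IMZ383 against the anaerobic reference (vertical axis), coloured by the comparison that called it. PHO5 and URA3 lie high in both, ACS1 and ACS2 low in both, and the labelled FDH1 probe set lies at -6.12 and 8.16. The other FDH1 probe set lies at -5.42 and 8.28. The point marked as having no gene is a probe set without annotation.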

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

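Of the tests in this part, those on the heme-dependent genes, on FDH1 and on sequence at PHO5 were chosen after the result was seen. The others were written before their own results, but the BioB split and the PHO5 pattern used in some of them had been read from the data. For the genes and lists that follow, the effect in IMZ305 differed from that in IMZ383 by a limma or camera test of the difference, in which genotype and oxygen differ together. The genes were picked from those called in opposite directions in both strain comparisons, and the lists from those called by camera in opposite directions in both. The difference was tested on the same arrays, so its p-values are no separate evidence for them. The log2 effect in IMZ305 minus that in IMZ383 was -14.29 for FDH1 (the more extreme of its 2 probe sets), -3.87 for NCA3, -2.42 for MBR1, -2.07 for DCS2 and -1.52 for YMR181C, each lower in IMZ305 and higher in IMZ383 than its reference. For FDH1 this size rests on the floor, since its signal in the anaerobic reference lay under the non-target controls. Among lists, the median difference was 0.93 for hypoxic genes (camera adjusted p = 9.90e-06; adjusted p = 0.136 with an estimated correlation) and -1.10 for stress and glycogen genes (camera adjusted p = 9.07e-11; adjusted p = 0.04 with an estimated correlation). It was -0.88 for thiamine and biotin genes (camera adjusted p = 3.11e-06; adjusted p = 0.04 with an estimated correlation) and 0.25 for ribosomal protein genes (camera adjusted p = 1.81e-05; adjusted p = 0.256 with an estimated correlation).

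Of the hypoxic genes, 7 of 22 rose in aerated IMZ305 (camera adjusted p = 0.00018, and adjusted p = 0.215 with an estimated correlation). A difference in hybridization, seen in the BioB control, was argued against as the whole cause: among the low-BioB arrays the median log2 change of the list was 0.473, against 0.536 over all arrays. Whether the IMZ305 cultures held less oxygen cannot be told apart from an effect of the genotype. Of 5 targets of the heme-dependent repressor Rox1, only AAC3 was called, with a rise of at least 1.63-fold. The log2 changes were 0.94 for ANB1, 0.45 for HEM13, -0.35 (SE 0.398) for COX5B and -0.21 (SE 0.231) for CYC7. The falls of COX5B and CYC7 were smaller than their SE. With a median of 0.454 and 1 called, the test could not decide. Dissolved oxygen was not among the values used here.

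FDH1 fell in IMZ305 and rose in IMZ383. The hybridization difference was argued against as the whole cause of the fall, since within the low-BioB arrays the smaller fall of its 2 probe sets was -5.424 on the log2 scale. Which of FDH1 and FDH2 gave the signal stays open: both probe sets moved alike, with the smaller fitted changes -5.423 in IMZ305 and 8.164 in IMZ383 (the latter set by the floor), but both may read the pooled signal, so moving alike decides nothing. Formate released by the introduced enzyme stays open as well: the one-carbon and formate list without FDH1 had a median log2 change of -0.2 in IMZ383, with 4 called lower. No biological explanation was tested for the fall in IMZ305.

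PHO5 gave signal in the engineered strains and none above background in the reference, where it lay under the highest non-target control on 6 of the 6 arrays and reached at most 0.6. A response of the phosphate genes cannot be told apart from other causes: the list without PHO5 had a median log2 change of -0.046 in IMZ305 and 0.06 in IMZ383, which the test took beforehand as evidence against it, but members were called both ways, such as PHO84 and PHO89 in IMZ383. A sequence or gene difference at PHO5 between the strain backgrounds, which the labels give as distinct, was not put to a test that could tell it from a silent gene, and background and engineering go together in the design.

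Other splits of the 6 arrays of a comparison gave at most 2 calls, against 1335 in the aerobic, 212 in the anaerobic and 3175 in the oxygen comparison. Each of those splits mixed arrays of both groups, so the group effect entered the spread and held the calls down. The low counts are therefore not a level for no effect. With 10 splits each and 1 as large as the real split, itself, a share under 0.05 cannot be reached. For the difference between the strain effects, 100 splits were used, with the real one put among them. Only the real one gave as many calls (823), and the highest other gave 652. Other splits could keep or swap whole the labels of 1 comparison and so carry its strain effect. The rank of the real split therefore cannot exclude chance.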

How the results depend on the processing

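The floors of 12 and 50, the BioB block and the ACT1 covariate were chosen after the data were seen, and the other alternatives before. No named gene that was called reversed its direction under the alternatives run, and no called list did under those run for lists: quantile normalization, the low-signal filter, the culture and BioB blocks and the estimated correlation. The 9 calls for deleted genes were kept in each alternative except the floor of 50, with 6 calls, where ALD2 and ALD3 in IMZ305, under the floor in both groups, and ACS1 in IMZ383 were no longer called. Of the named genes called, 82 of 137 in the aerobic, 22 of 82 in the anaerobic and 107 of 141 in the oxygen comparison were called in every alternative at the same threshold, and 100, 52 and 136 without any 1 array.

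Counts within 1.5 times those of the report are not repeated, and where no reason is given the cause was not tested. Quantile normalization gave 1367 lower probe sets in the oxygen comparison. Median centring gave 2228 higher and 1067 lower there, 87 higher in the anaerobic comparison and 27 in opposite directions in both strains; it shifts all values of an array alike. With 1 probe set per gene, 619 were higher without oxygen, with fewer tested. A fit to only the 2 groups compared, with fewer arrays, called 344 higher and 488 lower in IMZ305, 55 and 19 in IMZ383, and 14 in the same and 6 in opposite directions. With the culture number as a block, 28 were opposite. Array quality weights gave 870 higher in IMZ305, 276 higher and 117 lower in IMZ383, 1449 differences, and 79 in the same and 105 in opposite directions.

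A threshold of 2-fold, stricter by construction, left 267 higher and 295 lower in IMZ305, 88 higher in IMZ383, 623 and 1050 in the oxygen comparison, and 24 in the same and 14 in opposite directions. An adjusted p under 0.005 left 131 and 190, 39 and 11, and 507 and 1151, with 185 differences, 10 in the same and 3 in opposite directions. The floor of 50 gave 89 and 32 in IMZ383, 656 and 1362 in the oxygen comparison, and 25 and 26 in the same and opposite directions, and it set 33 named values to 0 where both groups lay under it. With the ACT1 3' to 5' ratio as a covariate, 95 were higher and 29 lower in IMZ383 and 25 in the same direction. Lists called by camera fell in number from 12, 19 and 15 to 3, 7 and 6 with an estimated correlation.

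Leaving out each array gave 277 to 587 higher and 389 to 741 lower in IMZ305, 93 to 179 and 36 to 71 in IMZ383, and 788 to 1011 and 1642 to 2165 in the oxygen comparison. Called differences ran from 479 to 997, probe sets in the same direction from 33 to 45 and in opposite directions from 18 to 53, and deleted loci stayed at 9. Of the probe sets of an array, 74.1% to 84.9% lay above the non-target controls, and folds against groups under them are lower bounds.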

Other observations

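The test of IMZ305 against the oxygen comparison and the choice of the probe set without a gene and of that shared by ALD2 and ALD3 were made after the values were seen, and the test of neighbouring genes before.

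Genes next to the deleted loci were tested for effects of the inserted markers. In IMZ305, 2 of 12 neighbours were called (16.7%, against 18.1% of other genes; Fisher's exact p = 1), FLC2 beside ACS1 with a log2 change of 1.08 and MFM1 beside ALD6 with 1.17. In IMZ383 it was 1 of 4, YLR152C beside ACS2 with 1.29 (25%, against 3.1%; Fisher's exact p = 0.118). With so few neighbours, an effect of the markers on single genes cannot be told apart from the effect of the strain.

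It was asked whether expression in aerobic IMZ305 lies closer to the anaerobic reference than shared reference arrays alone would give. The covariance of the log2 changes of IMZ305 and of the oxygen comparison was 0.3322 over 4478 probe sets, against at most 0.03028 in 100 simulations with the same arrays shared and no effect. The simulations held no effect in either comparison, while the data held many, and deleted genes with signal were kept. The test therefore shows only that the changes covary by more than the shared arrays give. It cannot decide whether IMZ305 as a whole shifted towards the anaerobic cultures. The correlation itself, 0.409, was under the mean of the simulations, 0.499, so it carries no information of its own. Oxygen supply in the cultures was not measured in the values used here.

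Of the probe sets with no gene in the annotation used here, the one with the largest rise in IMZ305 read 0.233 ± 0.0577 in the aerobic reference, 3670 ± 190 in IMZ305 (adjusted p = 1.04e-13), 0.3 in the anaerobic reference and 0.267 ± 0.115 in IMZ383. The probe set that the annotation gives to both ALD2 and ALD3 went from 188 ± 21.9 to 0.9 ± 0.656 in IMZ305 (adjusted p = 4.29e-09) and read 82.2 ± 6.8 and 107 ± 14.2 without oxygen (adjusted p = 0.296).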
